A study of Mus musculus with 6 samples.

How the data were processed

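RNA-seq had been performed on the striatum, the input nucleus of the basal ganglia, of C57 mice. There were 6 samples, 3 control and 3 overexpressing PDE5A, and each was placed in its group by its title. Per the labels' protocols, total RNA was isolated with Trizol and strand-specific libraries were prepared with a TruSeq kit. Each deposited file held whole-number counts per Ensembl gene for 1 sample, without normalization. Per the submitters' processing notes, FastQC 0.11.5, STAR 2.5.3a, Cuffnorm and DESeq 1.16.1 were used with genome build mm10. The notes assign no roles to these tools. The counting program, its strand setting and the annotation release are not given in the sources used here. How overexpression was brought about, and what the control animals received, is likewise not given in the sources used here. Because the strand setting is unknown, counts of overlapping and antisense genes are uncertain, as are those of genes with near-identical copies.

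The files held 55335 gene identifiers, of which 55154 were matched to a symbol in GENCODE release M21 for the same mouse assembly, from which coordinates were also taken. Identifiers with no match held at most 0.0129% of the counts of any library. Library totals ran from 33013698 to 42288789 counts, so counting error was small beside the differences between samples for all but the lowest genes. Replicates within a group differed by more than sampling noise, with a chi-square per degree of freedom of 20.8 to 55.5 over genes, so no pair was taken for repeat sequencing of one library, and the labels list each library as a sample of its own. Nothing in the labels says that the samples came from separate animals, and the p-values measure the spread between these samples, which may be technical.

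Differences between groups were tested with edgeR 4.0.16 in R 4.3.3, using TMM size factors, genes kept by filterByExpr, robust quasi-likelihood F-tests and Benjamini-Hochberg adjustment over the 19809 genes tested. The threshold was an adjusted p of 0.05 and all tests were two-sided. Fold changes are overexpression over control. Standard errors were derived from the test, as the absolute log2 fold change divided by the square root of the F statistic. CPM values use the TMM-adjusted library sizes unless summed over a family of genes, where they use the totals. Log2 CPM values had a prior count of 2. Pde5a was also compared with an exact permutation test.

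The tests, the naming of genes and 33 gene lists were fixed before the data were examined. The lists cover the cell types of the striatum and its surroundings, cyclic nucleotide signalling, neurotransmitter receptors, stress, immune response and energy metabolism. A further list of sex-linked genes served only as a check of the libraries. Each list was tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 33 lists. The estimated correlation and fry were used as alternatives, in the main fit of all 6 samples only. The level of a list in a library is the mean log2 CPM of its tested members. The rule for naming genes takes Pde5a, up to 12 genes per direction with the largest change among those past the threshold with at least 1 CPM and separate groups, and up to 3 members per list with the smallest p. Where fewer than 10 genes pass, it adds the 5 genes per direction with the smallest p. Unnamed gene models are passed over in the choice of largest changes. Genes named outside this rule are said to have been chosen after their values were seen.

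The tests were tried on simulated counts drawn for the 19809 genes from the means, dispersions and library sizes of this comparison, with 200 genes changed. The edgeR quasi-likelihood test recovered 75% of the genes changed 2-fold and 98% of those changed 4-fold, with 10 false calls among 183. The DESeq2 Wald test recovered 81% and 99% with 53 false calls among 233. The changed genes had at least 1 CPM and all genes varied independently, so these rates need not hold in the real data. There C4b, at a fold of 3.02, did not pass the quasi-likelihood test. With 1 of 33 simulated lists raised, camera called that list and 0 others when genes varied independently. In the real data the estimated inter-gene correlation was 0.98 for shared medium spiny neuron markers and 0.65 for interferon genes. It was 0.01 for the T cell list. The simulation therefore cannot show how often camera calls lists of correlated genes falsely.

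The alternatives fixed at the same time were DESeq2 size factors, upper-quartile factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter or a stricter filter on low counts, replicate number as a block, other thresholds, removal of mitochondrially encoded genes, another prior count, and each library left out in turn. Alternatives added after seeing the data were the edgeR likelihood ratio test, a fit without robust estimation, thinning of every library to the smallest total, the level of the cortical or the choroid plexus list as a covariate, and a fit without the 2 overexpression libraries high in choroid plexus markers. All 6 files were used.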

Results

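Transcript levels in mouse striatum were measured by RNA-seq in 3 control samples and 3 samples overexpressing PDE5A, a phosphodiesterase that hydrolyses cyclic GMP. The control libraries held 41720320, 42288789 and 40653784 counts in replicates 1 to 3, and the overexpression libraries held 39271447, 33013698 and 36921899. All 3 overexpression libraries were thus shallower than all 3 control libraries. Mitochondrially encoded genes took 9.58%, 11.6% and 10.6% of the counts in control and 9.77%, 10.4% and 9.005% in overexpression. In a check chosen after the values were seen, every library had at least 2628 counts of the Y-linked gene Ddx3y and at most 41 of Xist.

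The comparison asked which molecular changes occur in the striatum when PDE5A is overexpressed. Pde5a itself rose 147-fold, from 4.65 ± 1.26 CPM (SD, n = 3) in control to 684 ± 85.5 CPM (SD, n = 3) in overexpression. It was the only gene past the threshold among the 19809 tested. As groups, genes of the interferon response and of antigen presentation were higher in the overexpression samples, with positive fold changes for 25 of 25 and 17 of 17 members and medians of 1.20 and 1.29 on the log2 scale, although none of these genes passed the test over all genes. Camera called both lists with a preset correlation, while an estimated correlation gave adjusted p = 0.132 for each. Markers of T cells and infiltrating myeloid cells rose too (median 1.71), as did choroid plexus markers (3.21), the latter through 2 of the 3 overexpression libraries and with adjusted p = 0.349 with an estimated correlation. Markers of medium spiny neurons, the principal neurons of the striatum, had medians between −0.12 and −0.03 and no list of them was called, with medians from −0.68 to 0.20 in other settings.

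Pde5a (ENSMUSG00000053965) is a protein-coding gene on the plus strand of chromosome 3, from 122728947 to 122859374 in mm10. Its raw counts were 156, 170 and 246 in control replicates 1 to 3 and 30018, 23287 and 22170 in overexpression replicates 1 to 3. As the manipulated gene, Pde5a serves as a check of the labels. How overexpression was brought about is not given, so these counts cannot be assigned to the chromosomal gene or to an introduced copy. The log2 fold change was 7.20 with a standard error of 0.23. The 95% interval of the fold by a normal approximation, which is too narrow for so few samples, ran from 107 to 202. The adjusted p was 0.000151 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. An exact two-sided permutation test of the log2 CPM values gave p = 0.1, the smallest that 3 samples against 3 can give.

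**Figure D1:**
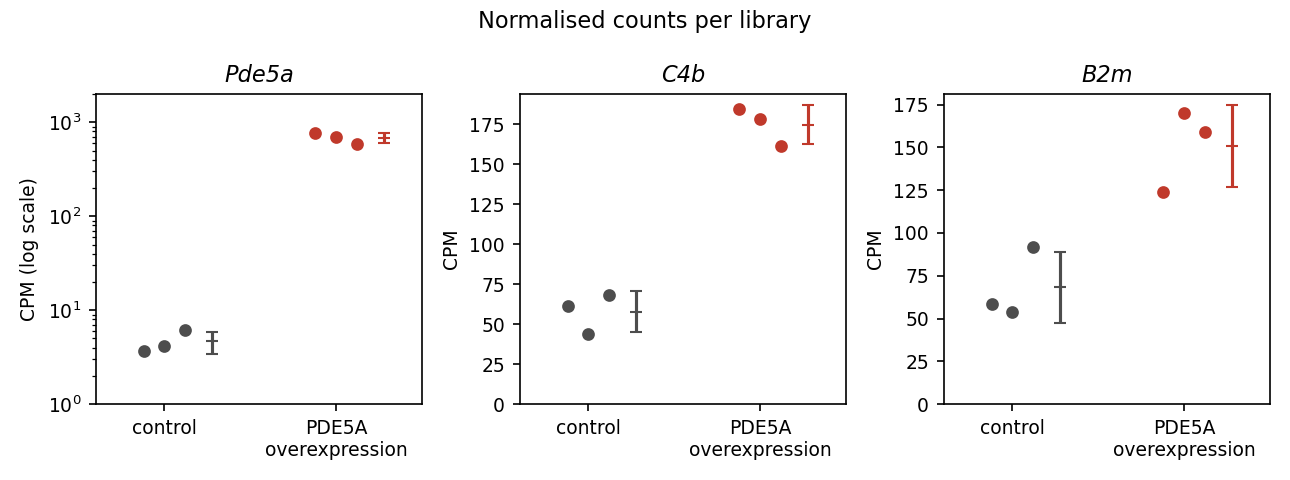
Normalised counts (CPM) of Pde5a on a log axis and of C4b and B2m on linear axes in the 3 control and 3 overexpression libraries, as points, with the group mean and SD beside them. Pde5a lies between 3.72 and 6.09 CPM in control and between 592 and 760 in overexpression, while C4b and B2m, which did not pass the threshold, show groups that do not overlap.

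No other gene passed, in either direction. At an unadjusted p under 0.05 there were 770 genes, 446 higher and 324 lower, where 990 would be expected by chance. The groups did not overlap for 1768 genes, 8.93% of those tested, where chance gives 10%. The DESeq2 Wald test called 83 genes, 76 higher and 7 lower. The genes with the smallest p after Pde5a included C3, the central complement component, at 1.56 ± 0.147 CPM in control and 5.53 ± 0.794 in overexpression (SD, n = 3), and C4b, another complement component, at 57.8 ± 12.7 and 175 ± 12.1 CPM. Their log2 fold changes were 1.83 (SE 0.19) and 1.59 (SE 0.16), with adjusted p of 0.0777 and 0.103 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. C4b has a near-identical neighbour, C4a, and its count is uncertain. The gene model F830016B08Rik had 0.130 ± 0.0300 CPM in control and 0.841 ± 0.0535 in overexpression. The immunoglobulin segment Igkv1-117, whose counts may be shared with related segments, had no counts in control replicates 1 and 2, 0.0742 CPM in control replicate 3, and 1.14, 2.56 and 1.34 CPM in overexpression. The pseudogene Gm10774 had at most 0.0247 CPM in any control library and at least 0.662 in any overexpression library, and it overlaps Usp50.

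The genes with the smallest p on the lower side did not pass either. Slc6a11, which encodes the GABA transporter GAT-3, had 166 ± 24.5 CPM in control and 112 ± 4.67 in overexpression, a log2 fold change of −0.57 (SE 0.11). Ngfr, the p75 neurotrophin receptor, had 9.37 ± 2.39 and 3.77 ± 1.13 CPM, and Cd36, a fatty acid transporter and scavenger receptor, had 1.32 ± 0.249 and 0.431 ± 0.0784 CPM. Crim1 had 46.7 ± 2.11 and 37.1 ± 1.47 CPM, and Usp50 had 2.35 ± 0.0640 and 1.15 ± 0.0488 CPM (SD, n = 3 throughout). Adjusted p values for these 5 genes ran from 0.607 to 0.780 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

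The interferon response list had the smallest camera p of the 33 lists. Over all genes 0 of its 25 members passed in edgeR's quasi-likelihood test, and 23 rose when adjusted over the list alone. The list had a camera adjusted p of 3.15e-55, and adjusted p = 0.132 with an estimated correlation. Gbp2, an interferon-induced GTPase, had 3.36 ± 0.435 CPM in control and 9.59 ± 2.39 in overexpression, a log2 fold change of 1.51 (SE 0.21). Oas1a, an activator of RNase L, had 0.408 ± 0.241 and 2.16 ± 0.953 CPM, with SD over 3 samples. Xaf1, an interferon-induced regulator of apoptosis, had a log2 fold change of 0.61 (SE 0.13). The mean level of the list was 1.31, 1.46 and 2.20 log2 CPM in control replicates 1 to 3 and 2.52, 3.25 and 2.81 in overexpression replicates 1 to 3. The number of members past the threshold when adjusted over the list alone depended on single libraries, while the list's median log2 fold change lay between 0.92 and 1.52 whichever library was left out. The number was 10 without control replicate 1, 8 without control replicate 2, 6 without overexpression replicate 2 and 10 without overexpression replicate 3. It was 1 with the level of the choroid plexus list as a covariate, where the interferon median was 0.998. Without the 2 overexpression libraries high in choroid plexus markers the interferon median was 1.02.

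The antigen presentation list also rose, with 13 of 17 members past the threshold when adjusted over the list alone and 0 over all genes. Its camera adjusted p was 3.36e-41, and adjusted p = 0.132 with an estimated correlation. B2m, the light chain of class I molecules, had 68.2 ± 20.6 CPM in control and 151 ± 23.9 in overexpression, a log2 fold change of 1.15 (SE 0.23). Psmb8, an immunoproteasome subunit, had 2.75 ± 0.472 and 8.15 ± 2.75 CPM. H2-K1, a class I heavy chain, had 29.0 ± 7.82 and 70.6 ± 13.6 CPM (SD, n = 3), a value made uncertain by its close relatives. With only genes of at least 1 CPM in all 6 libraries, 8 of the 11 members left passed when adjusted over the list alone.

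Markers of T cells, NK cells and infiltrating myeloid cells formed the only list called with either way of treating the correlation. Of 16 members tested, 15 had positive fold changes, 8 rose when adjusted over the list alone and 0 over all genes. The median log2 fold change was 1.71 and the camera adjusted p was 1.39e-23, with adjusted p = 0.0187 with an estimated correlation and 0.0412 with fry. The levels were low. The chemokine receptor Cxcr6 had 0.171 ± 0.0875 CPM in control and 0.967 ± 0.114 in overexpression, and the T cell receptor subunits Cd3g and Cd3e had 0.121 ± 0.0635 and 0.0898 ± 0.1002 CPM in control and 0.586 ± 0.188 and 0.718 ± 0.169 in overexpression (SD, n = 3). Whichever library was left out, camera with the preset correlation still called the list, with medians of 1.23 to 1.83. The estimated correlation and fry were not rerun in any other fit, so whether their calls depend on single libraries was not tested. The count of 8 became 1 without control replicate 1, 4 without control replicate 2 and 1 without overexpression replicate 2. It became 1 with the choroid plexus level as a covariate and 0 without the 2 libraries high in choroid plexus markers, where the list also stayed called, with medians of 1.37 and 1.41. With at least 1 CPM required in all 6 libraries only 2 members were left, at a camera adjusted p of 0.822.

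Among glial lists, reactive astrocyte genes rose, with 14 of 17 members positive, a median of 0.13, 3 past the threshold when adjusted over the list alone and 0 over all genes. Their camera adjusted p was 3.99e-06, and adjusted p = 0.288 with an estimated correlation. The 3 were the protease inhibitor Serpina3n, at 8.22 ± 2.18 CPM in control and 16.6 ± 2.34 in overexpression, and the intermediate filament genes Vim and Gfap, at 23.5 ± 3.40 and 174 ± 37.3 CPM in control and 33.3 ± 3.26 and 269 ± 29.6 in overexpression (SD, n = 3). The median of the reactive list lay between 0.13 and 0.37 in the 20 other fits. General astrocyte markers fell together, with 14 of 14 members negative, a median of −0.19, 0 past the threshold either over all genes or adjusted over the list alone, and a camera adjusted p of 3.76e-07, which was adjusted p = 0.292 with an estimated correlation. Aldoc had 680 ± 39.1 CPM in control and 588 ± 8.95 in overexpression.

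Activated microglia genes rose with a median of 0.24, a camera adjusted p of 8.11e-06, and adjusted p = 0.268 with an estimated correlation. The median was 0.45 without overexpression replicate 3 and 0.08 with the choroid plexus level as a covariate. Adjusted over the list alone, Cst7 and Lyz2 rose and Axl fell among 12 members, and 0 passed over all genes. Without the 2 libraries high in choroid plexus markers the list was not called, with a camera adjusted p of 0.295. General microglia markers had a median of 0.05 and a camera adjusted p of 0.0453, and adjusted p = 0.800 with an estimated correlation. Of 16 members, C1qa, a complement subunit, was the only one past the threshold when adjusted over the list alone, and 0 passed over all genes. C1qa had 44.5 ± 3.71 CPM in control and 58.9 ± 5.48 in overexpression. The microglia call was lost in 4 of the 6 fits that left out 1 library, the median was 0.16 with a camera adjusted p of 2.86e-06 without overexpression replicate 3, and the direction turned with the choroid plexus level as a covariate, to a median of −0.05, and without the 2 libraries high in that list, to −0.13.

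Choroid plexus markers had the largest median of the 33 lists, 3.21 on the log2 scale, and all 15 members had positive fold changes. The camera adjusted p was 6.04e-11, and adjusted p = 0.349 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone, with 6 at an unadjusted p under 0.05. The difference came from 2 libraries. The mean level was 1.24, 0.89 and 0.76 log2 CPM in control replicates 1 to 3, 2.77 and 5.10 in overexpression replicates 1 and 2, and 0.50 in overexpression replicate 3. Ttr, the thyroid hormone carrier made by the choroid plexus, had 48.5, 32.6 and 35.7 CPM in control and 481, 2243 and 22.5 CPM in overexpression. The list's median was 0.83 without overexpression replicate 2, 1.68 with limma-voom and −0.58 without overexpression replicates 1 and 2.

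Markers of neurons from neighbouring regions also differed between libraries. Thalamic markers fell, with 11 of 12 members negative, a median of −0.37 and a camera adjusted p of 6.15e-09, and adjusted p = 0.153 with an estimated correlation. Gbx2 and Prkcd, at 0.657 ± 0.132 and 25.3 ± 5.05 CPM in control and 0.219 ± 0.0364 and 14.6 ± 2.42 in overexpression, were the 2 members past the threshold when adjusted over the list alone, and 0 passed over all genes. Without control replicate 1 the thalamic median was −0.19. Glutamatergic cortical markers were called higher, with 16 of 16 members positive, a median of 0.39, a camera adjusted p of 0.0130, and adjusted p = 0.796 with an estimated correlation, and with 0 members past the threshold over all genes or adjusted over the list alone. Their level was 4.79, 3.08 and 5.49 log2 CPM in control and 4.18, 4.88 and 5.92 in overexpression, so the groups overlapped. The median became −0.03 without control replicate 2, −0.24 without overexpression replicate 3, 0.97 without control replicate 3 and 1.17 without the 2 libraries high in choroid plexus markers.

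**Figure D2:**
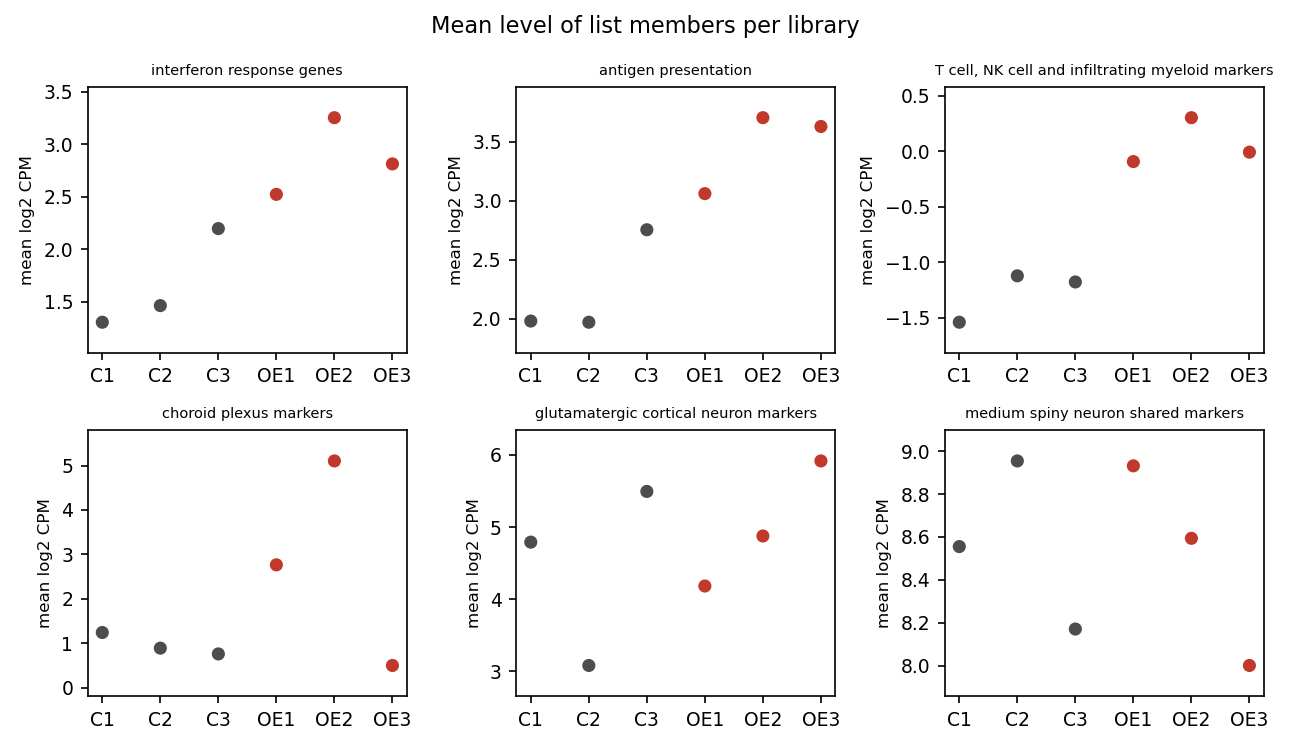
Mean log2 CPM of the members of 6 gene lists in control libraries (C1 to C3, grey) and overexpression libraries (OE1 to OE3, red), each panel with its own axis. The interferon response, antigen presentation and T cell lists lie higher in all 3 overexpression libraries than in any control library, choroid plexus markers are high in OE1 and OE2 only, and cortical and medium spiny neuron markers overlap between groups.

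Markers of medium spiny neurons and genes of cyclic nucleotide signalling were not called. The 22 markers shared by medium spiny neurons had a median of −0.03 with a camera adjusted p of 0.445. Markers of the direct-pathway (D1) and indirect-pathway (D2) neurons had medians of −0.05 and −0.12 with camera adjusted p of 0.472 and 0.0616. With the cortical level as a covariate the shared markers had a median of 0.17, and the direction was also positive without control replicate 2 (0.20) and without overexpression replicate 3 (0.18). When 1 library was left out, medians ran from −0.19 to 0.08 for D1 markers and from −0.31 to 0.10 for D2 markers, so their direction depended on single libraries. Of 20 other settings, 7 called the shared markers, 4 of them lower and 3 higher, while 6 called the D2 markers and 2 the D1 markers, all lower. The lowest medians, −0.60 for shared, −0.56 for D1 and −0.68 for D2 markers, came without the 2 libraries high in choroid plexus markers, and with the choroid plexus level as a covariate they were −0.29, −0.27 and −0.35. Of 22 genes of cGMP and nitric oxide signalling, 8 had positive fold changes, with a median of −0.04 and a camera adjusted p of 0.445. The median ran from −0.12 to 0.04 when 1 library was left out, and the list was called lower in 1 of 20 other settings, without the 2 libraries high in choroid plexus markers, with a median of −0.23 and a camera adjusted p of 0.0284. Prkg1, a cGMP-dependent kinase, had 8.84 ± 1.40 CPM in control and 7.12 ± 0.859 in overexpression, and Gucy1a1, a subunit of soluble guanylyl cyclase, had 155 ± 25.6 and 135 ± 24.2 CPM (SD, n = 3). The 16 cAMP-specific phosphodiesterases and adenylyl cyclases had a median of −0.01, a mean of 0.04 and a camera adjusted p of 0.587. In each of these 5 lists 0 members passed over all genes or adjusted over the list alone. Striatal interneuron markers were called lower, with 10 of 16 negative, a median of −0.31, a camera adjusted p of 0.0104, and adjusted p = 0.401 with an estimated correlation. Npy2r had 8.11 ± 1.05 and 4.50 ± 1.88 CPM, and 0 members passed over all genes or adjusted over the list alone. The interneuron call was lost without control replicate 2 and without overexpression replicate 3, with camera adjusted p of up to 0.147, and the median was −0.57 without the 2 libraries high in choroid plexus markers.

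GABA receptor and GABA handling genes fell by a small amount, with 13 of 19 negative, a median of −0.08, a camera adjusted p of 0.00462, and adjusted p = 0.258 with an estimated correlation. Slc6a11 was the member past the threshold when adjusted over the list alone, and 0 passed over all genes. The GABA median was −0.02 without overexpression replicate 2, with a camera adjusted p of 0.0487, and −0.14 without overexpression replicate 1. The 28 glutamate receptor and postsynaptic scaffold genes had a median of −0.02 and a camera adjusted p of 0.472. Immediate early genes, which respond to neuronal activity, were called higher with 17 of 18 positive, a median of 0.37, a camera adjusted p of 0.000121, and adjusted p = 0.488 with an estimated correlation. Fos had 5.06, 1.93 and 5.40 CPM in control and 2.91, 19.1 and 9.29 in overexpression, and without overexpression replicate 2 the list had a camera adjusted p of 0.310. Its median ran from 0.08 to 0.56 when 1 library was left out. It was also not called with the choroid plexus level as a covariate. Circadian clock genes had a median of 0.14, a camera adjusted p of 0.00737, and adjusted p = 0.349 with an estimated correlation, and 12 of 18 were positive. The circadian call was lost without control replicate 3 and without overexpression replicate 1, with camera adjusted p of up to 0.105, and the median was 0.09 without overexpression replicate 3. For the glutamate, immediate early and circadian lists 0 members passed over all genes or adjusted over the list alone.

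Of the other called lists, mitochondrially encoded protein genes fell, with 13 of 13 negative, a median of −0.15, a camera adjusted p of 3.55e-05, and adjusted p = 0.547 with an estimated correlation. That call was lost without control replicate 2, the library with the highest mitochondrial share, at a median of −0.06 and a camera adjusted p of 0.113, and the median was −0.30 without the 2 libraries high in choroid plexus markers. Oligodendrocyte precursor markers fell, with 10 of 13 negative, a median of −0.07, a camera adjusted p of 0.0104, and adjusted p = 0.303 with an estimated correlation. Pdgfra was the precursor gene past the threshold when adjusted over the list alone, at 62.7 ± 4.28 CPM in control and 49.5 ± 3.198 in overexpression, and 0 passed over all genes. The precursor list was called in 16 of 20 other settings. Its call was lost in 2 of the 6 fits that left out 1 library, with a camera adjusted p of 0.197 without control replicate 1. The median ran from −0.17 to −0.03 over these 6 fits. Meningeal fibroblast and extracellular matrix genes rose, with 15 of 17 positive, a median of 0.15, a camera adjusted p of 0.00516, and adjusted p = 0.189 with an estimated correlation. The meningeal list was called in 17 of 20 other settings, with medians of 0.12 to 0.30. Its call was lost without control replicate 3, at a camera adjusted p of 0.0771. Among the other losses was the fit without the 2 libraries high in choroid plexus markers. The median was 0.30 without overexpression replicate 1. Igfbp2 had 12.6, 45.7 and 13.2 CPM in overexpression, highest in the library that was highest in choroid plexus markers.

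Over all genes the DESeq2 Wald test called 10 members of the interferon list, 9 of antigen presentation, 2 each of reactive astrocyte and activated microglia genes, and 1 each of the T cell, thalamic and GABA lists, and 0 of any other list tested. The remaining lists were not called and had 0 members past the threshold over all genes or adjusted over the list alone. Camera adjusted p was 0.138 for cytosolic ribosomal proteins (median −0.02), 0.187 for heat shock and unfolded protein response genes (0.05), 0.253 for oligodendrocyte and myelin markers (−0.06) and 0.266 for nuclear-encoded oxidative phosphorylation genes (0.02). Camera adjusted p was 0.504 for pericyte and smooth muscle markers (0.05), 0.504 for erythrocyte genes (−0.00372), 0.745 for glucocorticoid-responsive genes (0.01) and 0.745 for endothelial markers (−0.01, with a mean of 0.01). Hypothalamic and septal markers and ependymal markers had medians of 0.01 and 0.02 but means of −0.19 and −0.15, with camera adjusted p of 0.253 and 0.445. In 20 other settings the ribosomal and ependymal lists were called in 4 each, the erythrocyte and hypothalamic lists in 2 each, and the oligodendrocyte, oxidative phosphorylation and endothelial lists in 1 each.

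**Figure D3:**
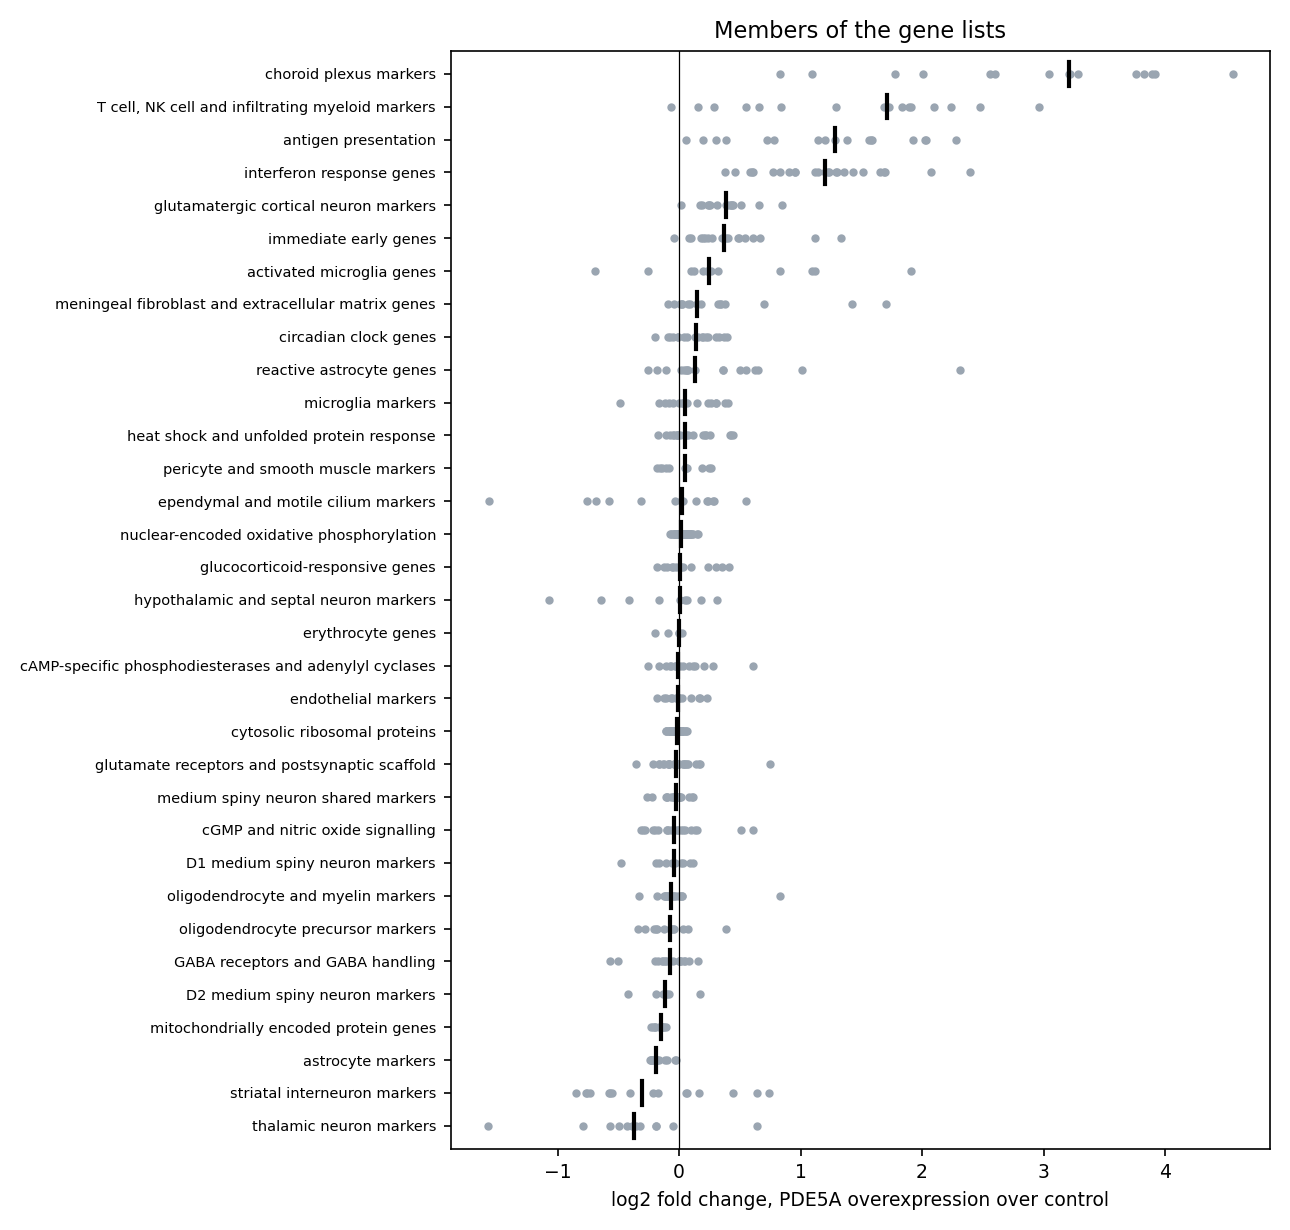
Log2 fold change, overexpression over control, of each tested member (grey points) of the 33 gene lists, with the median of each list as a black bar. The choroid plexus, T cell, antigen presentation and interferon lists have the highest medians, 3.21, 1.71, 1.29 and 1.20, and the thalamic and interneuron lists the lowest, −0.37 and −0.31.

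The libraries did not separate by group on the main axis of variation. The first principal component of the 1000 most variable genes held 41.4% of the variance and ran from control replicate 2 (−40.9) to overexpression replicates 2 (27.1) and 3 (27.3), with control replicate 3 at 7.08 above overexpression replicate 1 at −0.43. Pearson correlations of log2 CPM across genes were 0.978 to 0.985 within groups and 0.969 to 0.985 between groups.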

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

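The likelihood ratio test, the fit without robust estimation, thinning, both covariates and the fit without 2 libraries were chosen after the data were seen. Pde5a was past the threshold in all 20 alternative fits, with log2 fold changes from 6.99 to 7.44 and adjusted p of at most 0.0272 in the respective test with Benjamini-Hochberg adjustment. The count of 1 gene became 83 with the DESeq2 Wald test, 65 with the edgeR likelihood ratio test, 6 with the cortical level as a covariate, 5 with limma-voom, 5 without the 2 overexpression libraries high in choroid plexus markers, where the lone remaining library is assumed to vary like the controls, 3 with no filter and 3 at an adjusted p threshold of 0.1. The cause was not tested. In simulated data with independent genes the DESeq2 Wald test made 53 false calls among 233 and the quasi-likelihood test 10 among 183. The likelihood ratio test was not simulated, and these shares do not tell how many of the 83 calls are false. Leaving out 1 library gave 1 to 2 genes. Replicate number as a block gave 3 genes. Deviations of same-numbered samples correlated at −0.0202, 0.0272 and 0.292, and control replicate 1 correlated best with overexpression replicate 3, so the numbers were not taken to pair the samples. The 17 lists called became 1 with an estimated correlation and 1 with fry, and 14 to 19 when 1 library was left out. Adjusted over the list alone, interferon members past the threshold numbered 6 to 25 when 1 library was left out, 1 with the choroid plexus covariate and 9 without the 2 libraries. T cell list members numbered 1 to 7, 1 and 0 in these settings, and 0 of 2 with at least 1 CPM in all 6 libraries, where antigen presentation had 8 of 11. Direction turned for markers shared by medium spiny neurons, with a median of 0.17 with the cortical covariate, −0.25 to 0.20 when 1 library was left out and −0.60 without the 2 libraries. It also turned for endothelial markers (−0.0889 to 0.0827) and cortical markers (−0.24 to 0.97) when 1 library was left out. In these fits the median changed sign for 15 of the 16 lists not called, D1, D2 and cGMP genes among them, and for 2 of the 17 called. With the choroid plexus covariate and without the 2 libraries, medians were −0.0512 and −0.13 for microglia markers and 0.0542 and −0.58 for choroid plexus markers, where the covariate removes the list's own difference. Of 725 other results for lists, 632 kept their side of the threshold, 52 of these with a median of the other sign, while 56 lost the call, 27 gained it and 10 reversed. Of 2200 for named genes, 48 gained a call and 25 without a call changed sign. Genes with few counts, such as the T cell markers, limit what this depth can show.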

Other observations

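All tests in this part, the gene families and Slc17a7 were chosen after the data were seen, and only for the choroid plexus covariate and the splits of the samples for the lists and the interferon median was the meaning of each outcome written before its value was computed. Interferon-induced GTPases (guanylate-binding proteins and immunity-related GTPases), taken as a sum of 16 genes, had 43.5, 47.0 and 71.7 CPM in control replicates 1 to 3 and 98.0, 177 and 150 CPM in overexpression replicates 1 to 3. The ratio of geometric means was 2.61, with an exact two-sided permutation p of 0.1, the smallest that 3 samples against 3 allow. Of the 16 genes, 15 were higher under TMM, DESeq2 and upper-quartile scaling alike. The median log2 fold change over all genes was 0.0016 to 0.0087 under these scalings, so their agreement says little. Gbp2, Gbp3, Irgm1 and Iigp1 are also members of the interferon list, so this sum is no separate support for that list. Complement genes, taken as a sum of 13 genes, had 242, 201 and 249 CPM in control and 419, 417 and 360 in overexpression. The exact permutation test again gave p = 0.1. C4b, already seen among the smallest p values, alone had means of 57.8 and 175 CPM. It made up much of this difference, so the sum is no separate support for a change of the family. Several genes of both families have close relatives, and their single values are uncertain. Immunoglobulin gene segments summed to 32.7, 12.01 and 209 CPM in control and 164, 922 and 582 CPM in overexpression. Control replicate 3 lay above overexpression replicate 1, and the exact permutation p was 0.2. Of the 83 genes called by the DESeq2 Wald test, 19 were members of the interferon or antigen presentation lists, 15 carried names of interferon-induced GTPases or close relatives and 11 were immunoglobulin segments, 42 genes in all, since 3 were both list members and GTPases.

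Cortical and medium spiny neuron markers moved against each other across the 6 libraries. Pearson's r between the mean levels of the cortical list and of the shared medium spiny neuron list was −0.93 (exact permutation p = 0.00833) and Spearman's rho was −0.94 (exact permutation p = 0.0167), and r was −0.99 without the 2 libraries farthest from the median. The correlation was computed for no other pair of lists. Slc17a7, a cortical glutamate transporter gene, ranged from 64.3 CPM in control replicate 2 to 817 in overexpression replicate 3. Overlapping gene models sometimes traded counts between libraries while their sum stayed level. Among overlapping pairs with a level sum this was seen in 33 of 3786 (0.872%), against 21 of 10973 neighbouring pairs without overlap (0.191%), where level means a coefficient of variation of at most 12% and traded means a shift of at least 30 percentage points.

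Interferon and antigen presentation genes were higher in the overexpression samples, and the labels do not say whether both groups had the same procedure. Thinning every library to the smallest total left the median of the interferon list at 1.22. Thinning keeps each gene's expected share of its library, so the median was bound to change little and decides nothing about depth. Microglia and endothelial medians of at most 0.0485 argue against a larger share of those cells as the whole cause. With the choroid plexus level as a covariate the median was 0.998, with an SD over members of 0.45, against 1.20 and 0.50 without it, while members past the threshold when adjusted over the list alone went from 23 to 1 as the median standard error widened from 0.35 to 0.39 and residual degrees of freedom went from 4 to 3. RNA from infiltrating lymphocytes stays open. The T cell list without Cd4 gained 8.12 CPM while the antigen presentation list gained 249. Immunoglobulin gene segments, which the T cell list does not include, had mean sums of 84.7 CPM in control and 556 in overexpression. Their groups overlapped, so the T cell list alone does not measure what lymphocytes contributed. A response to PDE5A, or to whatever was done to bring about overexpression, may each be the source, and the design cannot separate them.

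Choroid plexus genes were high in overexpression replicates 1 and 2. All 15 members kept the order already seen in the mean of the list, with replicate 2 above replicate 1 above the other 4 libraries. Tissue carried into these libraries at dissection and a coordinated change of these genes would both give that order, so the source stays open. Pde5a was at 592 CPM in overexpression replicate 3, where Ttr was at 22.5 CPM.

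The pseudogene Gm10774 (chromosome 2, 126709354 to 126709557, minus strand in mm10) lies within Usp50 (126709096 to 126783470) and was higher where Usp50 was lower. The log2 fold change of their summed counts was −0.22 (SE 0.18), against −1.04 for Usp50 alone. A candidate explanation is that reads were assigned to either gene model, although what would make this differ by group was not tested.

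With 10 ways to split 6 samples into groups of 3, no share under 0.05 can be reached. The number of genes past the threshold was 1 in the real split and up to 5 in others, with 3 of the 10 splits giving as many. The number of lists called by camera was 17 in the real split and 10 to 19 in others, again with 3 of the 10 splits giving as many. The median of the interferon list was 1.20 in the real split and at most 0.96 in size in others. Of the 10 splits, 1, the real one, gave as much. The 0.96 came from control replicates 1 and 2 with overexpression replicate 1 against the rest. That split also gave 3065 genes at an unadjusted p under 0.05. Control replicates 1 and 3 with overexpression replicate 3 against the rest gave 2520, against 770 in the real split. These counts point to a structure of the samples other than the groups. The interferon level differed along the split with 3065 genes as well as between the groups.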
